A study of Mus musculus with 10 samples.

How the data were processed

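RNA-seq and iCLIP were measured in mouse V6.5 embryonic stem (ES) cells. For RNA-seq, cells carried lentiviral hairpins against Rbfox2 (shFox2-1 or shFox2-2) or control hairpins against luciferase (shLuc) or GFP (shGFP). Each hairpin was used in biological duplicate, which gave 8 poly(A)-selected paired-end libraries. Cells were harvested after 3 days in puromycin at 1 µg/ml and 24 h without it, per the labels' protocols. For iCLIP, which maps RNA crosslinked to a protein in living cells, human RBFOX2 with or without a FLAG-HA tag was induced by doxycycline at 1 µg/ml for 24 h. Cells were irradiated at 150 mJ/cm2, and RNA fragments were recovered by serial FLAG and HA immunoprecipitation. The tagged and the untagged library were each amplified for 16 cycles, and the untagged library for 7 more, per the labels' protocols.

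Expression was given by the authors as FPKM (fragments per kilobase of transcript, scaled to the fragments mapped) with a lower and an upper confidence bound and a status, 1 value per gene and hairpin, per the file headers. The table has the layout of a Cuffdiff gene table, and the 2 libraries of a hairpin were pooled in each value. TopHat2 2.0 and Cufflinks 2.1.1 and the mouse build mm9 were named in the submitters' processing notes. The annotation and the scaling between hairpins were not given in the sources used here. The bounds lay symmetrically about the FPKM value except where the lower bound was 0. Sequencing depth was unknown, since FPKM values were given without counts. Above 5 FPKM the median distance from the value to its bound was 13.8% of the value for shLuc, 15.3% for shGFP, 14.9% for shFox2-1 and 17.5% for shFox2-2.

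Binding was given by the authors as clusters of the tagged iCLIP library, each with a position on mm9, a gene ID, a coverage, a fold enrichment over the untagged library and a q-value, per the file headers. The clusters had already been filtered for enrichment over the untagged library. The aligner and the cluster caller were not given in the sources used here. Coverage, fold and q-value were used only to describe and rank clusters within this list. PCR copies had not been shown to be independent molecules, so intervals on shares cover counting error only.

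The test design written before the data were examined assumed a deposited comparison with q-values. The table held no such columns, so limma 3.58.1 (R 4.3.3) with a mean-variance trend was run on log2(FPKM + 1), 2 knockdown against 2 control hairpins. Fold changes on this scale understate the change of genes with low FPKM. Because duplicates were pooled, the limma p measures the spread between hairpins and not between cultures. Of 26857 entries, 105 had a failed status and 6477 were at 0 FPKM in every hairpin (a few met both criteria), and the remaining 20281 were tested. A low-data status in some hairpin, as for Rbfox2, was found in 2939 of them, which were kept. Of these, 12632 had a mean FPKM of at least 1 and are called expressed. P-values were adjusted by the Benjamini-Hochberg method.

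As a second criterion, chosen after seeing the data, a gene was called separated when the intervals of both knockdown hairpins lay above, or both below, the intervals of both control hairpins. This was computed over the expressed genes and took the place of the q-value in the rule for named genes. By that rule the text names the 10 largest rises and 10 largest falls with a mean FPKM of at least 5, and up to 4 separated members of each gene list. It names 2 members of highest FPKM where a list had none, up to 8 separated members of the RNA-binding protein lists, the 10 genes with the most clusters and the 5 clusters with the highest coverage.

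Before the data were examined, 27 gene lists were fixed. They covered the Rbfox family, SR proteins, hnRNP proteins, other splicing regulators, the spliceosome core, nonsense-mediated decay (NMD) and the exon junction complex, other mRNA-binding regulators and RNA-binding proteins known to make NMD isoforms. The remaining lists covered pluripotency, neural and ectoderm, mesoderm, endoderm, trophoblast, fibroblast, the 2-cell-like state, p53 targets, interferon response, unfolded protein response, cell cycle, actin cytoskeleton and adhesion, neuronal and synaptic genes, glycolysis and hypoxia, cholesterol synthesis, imprinted genes, mitochondrially encoded genes, replication-dependent histones and cytosolic ribosomal proteins. The first 7 lists were joined as the RNA-binding protein (RBP) lists, with 233 genes. Of 714 list genes, 690 were found after older names had been matched through the reference gene tables. No mitochondrially encoded gene was found, so that list gave no test. A current symbol was found for 95.1% of expressed entries.

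A list's median log2 fold change was compared with 10000 random lists of tested genes matched on decile of FPKM, two-sided, and adjusted over 26 lists (the joined RBP lists included) with at least 5 tested members. Separated against other genes were compared by two-sided Fisher's exact test. Genes are the units of both, so these describe a list against other genes in these pooled values and are not tests over cultures. Clusters were assigned to genes by at least 1 bp of overlap with the locus in the expression table, on either strand. Shares of genes with clusters were tested with 100000 permutations, and medians with 10000, within strata of FPKM decile and locus length decile, two-sided. Shares have exact (Clopper-Pearson) 95% intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

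The procedures were tested on simulated data. For knockdown against control hairpins, with 200 of 12632 genes changed, limma recovered 5.0% of changed genes at 1.5-fold, 71.5% at 2-fold and 91.0% at 3-fold, with 8, 16 and 16 false calls. Interval separation recovered 27.5%, 67.0% and 88.5%, with 5, 8 and 6 false calls. Over 12632 genes the list test called 98.0% of lists shifted by 0.15 log2 and 3.0% of unshifted lists. The share test called 99.5% with a further 0.02 of bound genes in the list and 3.5% without. The median test called 95.0% with bound genes shifted by 0.02 log2 and 7.5% without. Each gene had independent noise in these 3 simulations. Their false rates therefore do not cover genes that move together or differences between hairpins.

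Alternatives set before the data were examined were other thresholds, a minimum fold of 1.5, FPKM minimums of 1 and 5, no pseudocount, centring on the median gene, matching on locus length, clusters in the upper part of the coverage distribution, clusters wholly inside exactly 1 locus, at least 3 clusters against 0 and strata of FPKM only. Leaving out each hairpin in turn, genes with status OK in every hairpin and the submitters' gene ID of each cluster were added after seeing the data. Motif content, exon and intron annotation and gene strand were not analysed here, since no mm9 genome or annotation was used. Per-library tests were not run, because the values pool the libraries.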

Results

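Rbfox2 is an RNA-binding protein that regulates alternative splicing, and the series asked how it acts on the mRNAs of other RNA-binding proteins in mouse ES cells. The data comprised 8 RNA-seq libraries, 2 for each of 4 hairpins, and 2 iCLIP libraries. The expression values pool the libraries of a hairpin, so knockdown and control conditions had 2 values each. Each value is given with the deposited interval of its FPKM. The iCLIP data consisted of the clusters of 1 tagged library that were enriched over 1 untagged library, with no replicate. Depth was unknown for both assays.

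The targeted gene was examined first. Rbfox2 (listed as Rbm9, mm9 chromosome 15, 76912769 to 77137358) stood at 24.7 FPKM in shLuc (interval 21.9 to 27.4) and 23.3 in shGFP (20.6 to 26.0). It fell to 8.56 FPKM in shFox2-1 (7.14 to 9.98) and 7.21 in shFox2-2 (5.59 to 8.82). The knockdown mean was 32.9% of the control mean. The log2 fold change was -1.496 with a standard error of 0.14, and the limma adjusted p was 0.0471 over the 12632 expressed genes. Over all 20281 tested genes the limma adjusted p was 0.913, with an unadjusted p of 6.82e-05, against 3.73e-06 in the separate fit over expressed genes. The paralog Rbfox1 lay between 0.068 and 0.254 FPKM in the 4 hairpins, with every lower bound at 0, and Rbfox3 was not analysed here.

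Rbfox2 was 1 of 37 expressed genes that lay outside both control intervals in both knockdown hairpins. Among the genes that rose were Rbpj, the DNA-binding effector of Notch signalling, and Mdm2, the ubiquitin ligase that limits p53. Rbpj stood at 33.6 and 33.5 FPKM in the controls, 58.4 in shFox2-1 and 40.95 in shFox2-2. Mdm2 stood at 36.1 and 38.1 FPKM in the controls and at 55.6 and 49.5 in the knockdown hairpins. The largest rise by log2 fold change was that of Wdr35, part of the intraflagellar transport machinery, at 0.55 (standard error 0.13). Sar1a, a GTPase of vesicle transport, rose by 0.47 and Limk2, a kinase of cofilin, by 0.46. Tsn, which encodes translin, rose by 0.42 and Calu, a calcium-binding protein of the secretory pathway, by 0.38. Rises of 0.37 each were found for the ubiquitin ligase gene Rnf114, the splicing factor gene Srsf7 and the p38 kinase gene Mapk14.

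After Rbfox2, the largest fall was that of Trh, which encodes the precursor of thyrotropin-releasing hormone. Trh stood at 83.4 and 73.2 FPKM in the controls, 30.1 in shFox2-1 and 53.5 in shFox2-2, a log2 fold change of -0.94 (standard error 0.27). The integrin gene Itga3 fell from 24.4 and 26.2 FPKM to 15.0 and 11.9, a log2 fold change of -0.87. The transcription factor gene Sox4 and the actin-bundling gene Pls3 each had a log2 fold change of -0.60. Falls were also found for Ptms, which encodes parathymosin (-0.53), and Slc1a5, a neutral amino acid transporter (-0.41). Gm8292, a predicted gene (-0.68), and the pseudogene Dnmt3b-ps1 (-0.65) also fell, and their values are uncertain because related copies can share reads.

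Of the 37 separated genes, 22 were higher and 15 lower, with a median absolute change of 30.5%. The other 2 ways of pairing the 4 hairpins separated 3 and 16 genes. With hairpins centred on the median gene, 28 were higher and 9 lower, 22 of the 37 were separated in the same direction, and Tsn, Calu, Rnf114, Sox4 and Slc1a5 were among those that were not. By limma no gene passed an adjusted p of 0.05 over 20281 genes, and 908 had an unadjusted p under that value, 467 higher and 441 lower.

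**Figure D1:**
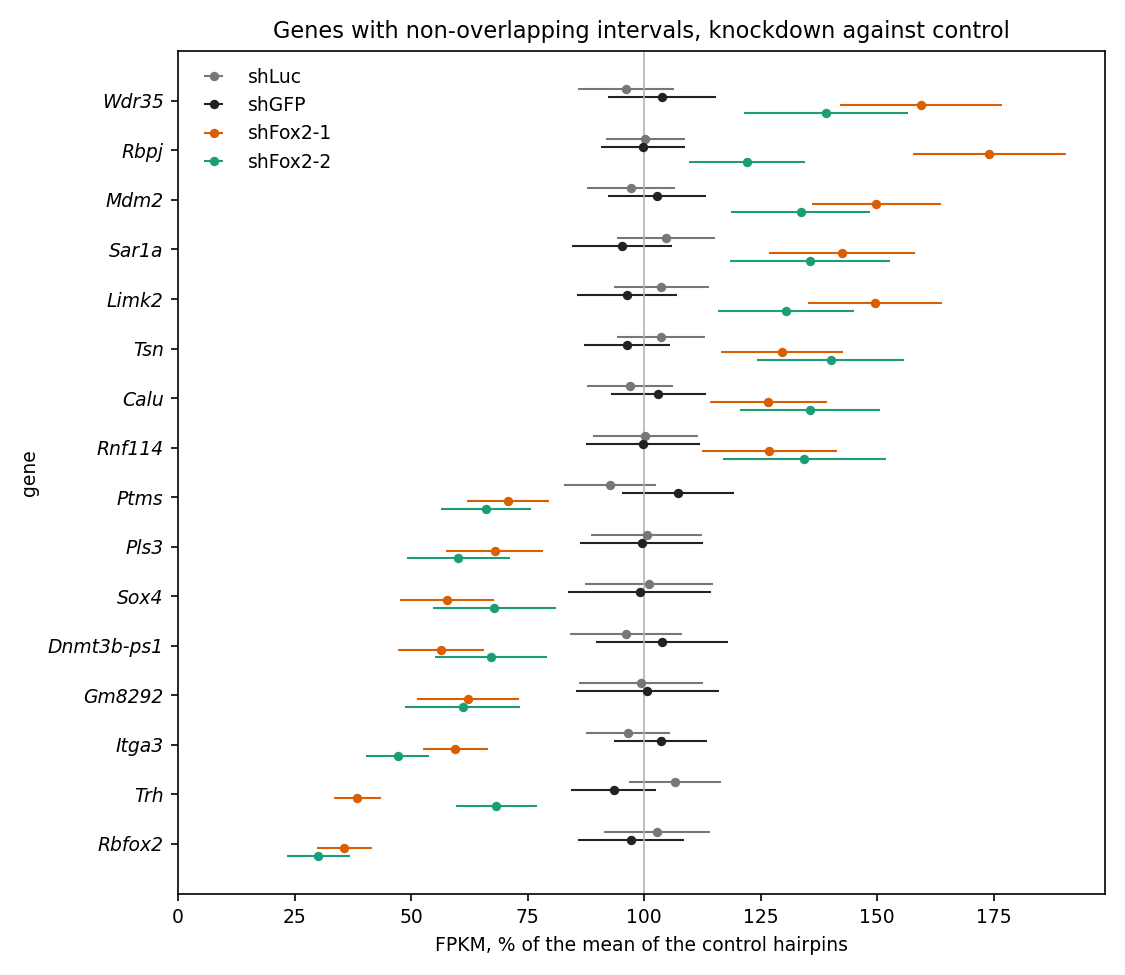
FPKM of the 8 largest rises and the 8 largest falls among separated genes, as a percent of the mean of the control hairpins, with the deposited interval of each hairpin as a bar. Rbfox2 lies at 35.7% in shFox2-1 and 30.0% in shFox2-2, and in each gene both knockdown intervals clear both control intervals.

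RNA-binding protein genes were examined as the group named by the study. Of 221 expressed members of the RBP lists, 5 were separated, Rbfox2 lower and Srsf7, Hnrnpab, Hnrnpa2b1 and Pcbp2 higher. Srsf7 stood at 100.2 and 97.9 FPKM in the controls and at 136 and 122 in the knockdown hairpins. The hnRNP genes Hnrnpab, Hnrnpa2b1 and Pcbp2 (the last encoding a poly(C)-binding protein) had log2 fold changes of 0.29, 0.28 and 0.25. Hnrnpa2b1 stood at 333 and 329 FPKM in the controls and at 410 and 397 in the knockdown hairpins. Under permutation within strata of FPKM and length, 1.44 of the separated genes were expected among RBP genes (p = 0.0128), and 1.09 of the higher ones against 4 observed (p = 0.0208). By Fisher's exact test separated genes were overrepresented among hnRNP proteins (3 of 26, adjusted p = 0.000348), RBPs known to make NMD isoforms (3 of 32, adjusted p = 0.000348) and the joined RBP lists (adjusted p = 0.000455). The targeted Rbfox2, whose fall the knockdown sets, is counted in the last pair of groups and among the 5 genes, and not among the 4 higher ones. The Fisher's tests ran over all 20281 tested genes, although only the 12632 expressed genes could be separated. They were not matched on FPKM either, so their p-values do not allow for the level of expression. After centring, Hnrnpab and Pcbp2 were not separated, and 5 RBP genes, Rbfox2 among them, were, against 1.48 expected (permutation p = 0.0143). With status OK required in every hairpin, which leaves out Rbfox2, 3 RBP genes were separated against 0.912 expected (permutation p = 0.0602).

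With all 4 hairpins the RBP lists as wholes did not stand apart from random lists of like expression. The joined lists were called in opposite directions by hairpin, with a median of -0.15 without shFox2-1 (adjusted p = 0.0052) and 0.14 without shFox2-2 (adjusted p = 0.00173). Without shFox2-2, SR proteins (0.26) and RBPs known to make NMD isoforms (0.20) were also called (adjusted p = 0.0052 each), as were other splicing regulators (0.15, adjusted p = 0.0383). Without shFox2-1 the spliceosome core (-0.17) and other mRNA-binding regulators (-0.16) were called lower (adjusted p = 0.0156 each). The joined lists had 115 members higher and 110 lower, with a median log2 fold change of 0.0027 (adjusted p = 0.799). SR proteins had a median of 0.09 (adjusted p = 0.189), with 11 of 13 members higher, and hnRNP proteins of 0.03 (adjusted p = 0.799), with 14 of 26. RBPs known to make NMD isoforms had a median of 0.04 (adjusted p = 0.751). The values are per gene, so the share of such isoforms was not measured. The spliceosome core had a median of -0.04 (adjusted p = 0.146), with 28 of 44 members lower. In that core Snrnp70, a U1 snRNP protein, stood at 173 and 172 FPKM in the controls and 154 and 189 in the knockdown hairpins. Snrpd3, an Sm protein gene, stood at 175.9 and 175.0 against 142 and 153. Medians were 0.01 for other splicing regulators (adjusted p = 0.799), 0.0027 for other mRNA-binding regulators (adjusted p = 0.969) and -0.01 for NMD and exon junction complex genes (adjusted p = 0.892). The most abundant members of these 3 lists included Srrm2 (log2 fold change 0.10), Puf60 (0.07), Caprin1 (0.25), Ybx3 (0.04), Casc3 (0.06) and Upf1 (-0.13), none of them separated. Adjusted over the list alone, limma called 1 gene in the Rbfox family, 1 in the joined RBP lists and 1 among RBPs with NMD isoforms, each time Rbfox2, and 0 in the other RBP lists.

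Gene lists outside the RBP group were compared in the same way, and members named here beyond the rule were chosen after their values were seen. Genes of the p53 response lay higher, with a median log2 fold change of 0.21 (adjusted p = 0.0013, from a permutation p of 0.0002, the smallest that the random lists could give) and 18 of 24 members higher. Mdm2 was the separated member. Perp, a p53 target in apoptosis and adhesion, stood at 10.8 and 10.6 FPKM in the controls, 26.4 in shFox2-1 and 13.5 in shFox2-2. Plk2, a polo-like kinase, stood at 5.22 and 6.19 against 10.1 and 7.36. The list's median was 0.29 in shFox2-1 and 0.03 in shFox2-2 as deposited, and the list lost its call without shFox2-1. Centred on the median gene, it lay at 0.29 and 0.21 over shLuc and shGFP in shFox2-1, and at 0.18 and 0.07 in shFox2-2. The 2 knockdown hairpins differed in this list (adjusted p = 0.0468 against matched random lists).

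Trophoblast markers also lay higher, with a median of 0.25 (adjusted p = 0.0013) and 10 of 15 members higher. Krt8 and Krt18, keratins of simple epithelia, led the list by level. Krt8 stood at 19.5 and 20.8 FPKM in the controls, 39.0 in shFox2-1 and 23.1 in shFox2-2, and Krt18 at 13.4 and 15.1 against 23.1 and 13.5. The list's median was 0.36 in shFox2-1 and -0.07 in shFox2-2, and without shFox2-1 its adjusted p was 0.675. Genes of the 2-cell-like state, a rare transcriptional state of ES cultures, had a median of 0.13 (adjusted p = 0.00607) with 12 of 13 members higher. Zscan4d was listed at 0 in both controls and at 0.572 and 0.401 FPKM in the knockdown hairpins, and it alone was called when limma was adjusted over the list alone. Gm4340 stood at 0.203 and 0.260 FPKM against 0.908 and 0.554, and Eif1a, the 1 expressed member, at 36.5 and 39.4 against 56.3 and 30.9. Zscan4 genes form a family of near-identical copies that can share reads, and without shLuc the list's adjusted p was 0.136.

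Cholesterol synthesis genes lay lower, with a median of -0.20 (adjusted p = 0.0013) and 22 of 23 members lower. Idi1, an isomerase of the pathway, stood at 66.9 and 67.6 FPKM in the controls, 42.4 in shFox2-1 and 65.5 in shFox2-2. Sqle, the squalene epoxidase, stood at 48.9 and 53.8 against 34.3 and 57.8, and the regulator Srebf2 at 27.9 and 30.7 against 21.6 and 24.0. The list's median was -0.37 in shFox2-1 and -0.04 in shFox2-2, and without shFox2-1 its adjusted p was 0.471. The other 2 ways of pairing the hairpins, which do not group the knockdowns, also called this list, with medians of 0.25 and -0.21 (adjusted p = 0.00104 and 0.0013).

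Cytosolic ribosomal protein genes had a median of -0.16 (adjusted p = 0.0013), with 43 of 52 members lower. In 30 of the 52, both knockdown values lay below both control values, where 16.7% would be only if hairpins were interchangeable. Over all expressed genes 2243 of 12632 were ordered so. The pairing of shGFP with shFox2-1 ordered 4597 genes higher and 776 lower, and genes of 1 list can move together. The 16.7% is therefore no firm reference for this list. Rpl27 stood at 24.1 and 23.6 FPKM in the controls and at 17.0 and 17.3 in the knockdown hairpins, while the abundant Rpl8 stood at 579 and 691 against 587 and 546. Their many processed pseudogenes can share reads. The list's median was -0.12 in shFox2-1 and -0.13 in shFox2-2 as deposited, and the list lost its call without shFox2-1. Centred on the median gene, it lay at -0.18 and -0.21 over shLuc and shGFP in shFox2-1. In shFox2-2 it lay at -0.08 and -0.01. The 2 knockdown hairpins differed in this list (adjusted p = 0.0143 against matched random lists).

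Genes of glycolysis and hypoxia had a median of -0.12 (adjusted p = 0.00607), with 19 of 25 members lower. Bnip3, a mitophagy receptor induced by hypoxia, stood at 11.8 and 13.0 FPKM in the controls and 6.78 and 7.82 in the knockdown hairpins. Tpi1, the triose phosphate isomerase, stood at 79.4 and 91.6 against 54.9 and 64.6. The most abundant members Aldoa and Eno1 had log2 fold changes of -0.12 and -0.11. Genes of the unfolded protein response had a median of -0.12 (adjusted p = 0.00891), with 19 of 23 lower. Its most abundant member, the asparagine synthetase gene Asns, went the other way at 117 and 121 FPKM against 134 and 148.3. Psat1, an enzyme of serine synthesis, stood at 92.8 and 110 against 80.0 and 97.5. Without shFox2-1 the median was -0.08 for glycolysis and hypoxia (adjusted p = 0.863) and -0.08 for the unfolded protein response (adjusted p = 0.994). Without shLuc that of glycolysis and hypoxia was -0.15 (adjusted p = 0.0594), and without shGFP that of the unfolded protein response was -0.04 (adjusted p = 0.110).

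Neuronal and synaptic genes, most of them at low FPKM, had a median of -0.12 (adjusted p = 0.0416) with 19 of 24 lower. Among genes with a mean FPKM of at least 1 their median was -0.14, and the list was not called (adjusted p = 0.115). The ankyrin gene Ank2 stood at 7.37 and 5.97 FPKM in the controls against 4.11 and 8.43. Cell cycle genes had a median of -0.08 (adjusted p = 0.0416) with 21 of 29 lower, 0.05 in shFox2-1 and -0.20 in shFox2-2. Their most abundant members Mcm2 and Cdc20 had log2 fold changes of 0.06 each. The neuronal list had a median of -0.07 without shFox2-1 (adjusted p = 0.930) and of -0.11 without shLuc (adjusted p = 0.137) or without shGFP (adjusted p = 0.0520). The cell cycle list had 0.05 without shFox2-2 (adjusted p = 0.660), -0.01 without shGFP (adjusted p = 0.113) and -0.15 without shLuc (adjusted p = 0.0537).

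Pluripotency genes had a median of 0.07 (adjusted p = 0.0889), with 23 of 34 higher, and Sall4, a zinc finger factor of ES cells, was the separated member at 70.98 and 72.3 against 91.4 and 87.7 FPKM. The pluripotency list was called higher without shGFP (0.14, adjusted p = 0.0121) and without shFox2-2 (0.31, adjusted p = 0.00104), and lower without shFox2-1 (-0.20, adjusted p = 0.0156). Replication-dependent histones had a median of 0.07 (adjusted p = 0.0889), and Hist1h4c was called when adjusted over the list alone, at 1.09 and 1.00 FPKM against 0.295 and 0.108. Its mRNA normally lacks a poly(A) tail and has near-identical copies. The most abundant histone genes, Hist1h2ad and Hist1h4i, had log2 fold changes of -0.02 and 0.08. Markers of other lineages did not stand apart with all 4 hairpins, with medians of -0.06 for neural and ectoderm (adjusted p = 0.189, 18 of 24 lower), -0.04 for mesoderm (0.751), 0.02 for endoderm (0.799) and 0.01 for fibroblast (0.799). Without shFox2-1 the neural and ectoderm list was called lower (-0.19, adjusted p = 0.0156). Among their most abundant members, log2 fold changes were 0.05 for Tubb3, 0.13 for Snai1, 0.05 for Gata2, 0.07 for Sparc, 0.01 for Lamc1, -0.09 for Fn1 and -0.10 for Tagln. Actin cytoskeleton and adhesion genes had a median of -0.01 (adjusted p = 0.751), with the nonmuscle myosin gene Myh10 separated at -0.31. Interferon response genes had a median of 0.01 (adjusted p = 0.799), with Bst2 at -0.70 and Ifitm3 at -0.18. Imprinted genes had a median of 0.02 (adjusted p = 0.799), with Gnas at -0.10 and Snrpn at 0.07. Against the control mean their median was -0.15 in shFox2-1 and -0.11 in shFox2-2 as deposited, and both knockdown values lay below both controls in 9 of 22 members and above in 0. Centred on the median gene, the list lay at -0.21 and -0.22 over shLuc and shGFP in shFox2-1, and at -0.02 and -0.04 in shFox2-2. The 2 knockdown hairpins differed in it (adjusted p = 0.0241 against matched random lists). Without shFox2-2 the list was called lower (adjusted p = 0.0013).

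Over these lists, 9 of 26 were called, and the other 2 ways of pairing the hairpins called 12 and 9. Of the 9, both other pairings called cholesterol synthesis and glycolysis and hypoxia, and 1 of them called trophoblast, the unfolded protein response, the cell cycle and ribosomal proteins. Neither called p53 targets, the 2-cell-like state or neuronal and synaptic genes. Adjusted over the list alone, limma called 0 genes in the lists for which no such gene is named.

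**Figure D2:**
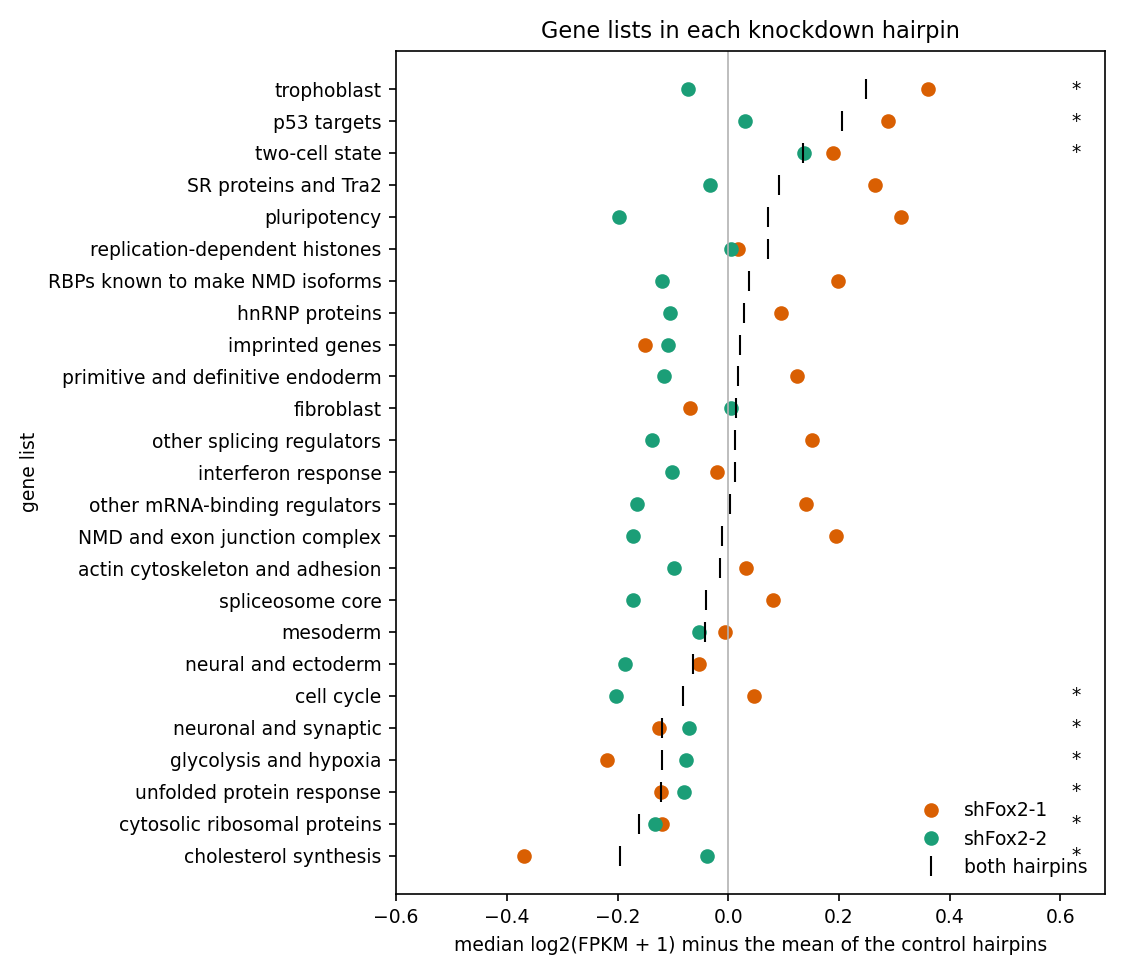
Median over each tested gene list of log2(FPKM + 1) in a knockdown hairpin minus the mean of the control hairpins, with a tick for the median of the fold change over both hairpins and an asterisk for lists with an adjusted p under 0.05. The pluripotency list lies at 0.31 in shFox2-1 and -0.20 in shFox2-2, while ribosomal protein genes lie at -0.12 and -0.13, all as deposited. Centred on the median gene, ribosomal protein genes lie at -0.18 and -0.21 over shLuc and shGFP in shFox2-1, and at -0.08 and -0.01 in shFox2-2.

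Agreement between the knockdown hairpins was examined next. Relative to both control intervals, 687 genes were higher in shFox2-1 and 44 in shFox2-2, and 22 were shared, among them Mdm2, Rbpj and Srsf7. Lower genes numbered 267 and 250, and 15 were shared, among them Rbfox2, Itga3 and Sox4. Independent lists of these sizes would share 2.39 higher and 5.28 lower genes. Both lists use the same controls, which raises their overlap, so the excess is not read as a shared effect. The counts are as deposited. The median log2 offset from a gene's mean over the 4 hairpins was 0.074 in shFox2-1 and -0.082 in shFox2-2. This offset can widen the gap between 687 and 44, and centred counts per hairpin are not given here. Simulated unchanged hairpins against these controls shared 3.56 higher and 4.64 lower genes, but from lists of 81.1 and 48.5 higher and 90.3 and 64.4 lower genes, so these values are no reference for lists of the sizes observed. Across 12632 genes, which are not independent replicates, the fold change of shFox2-1 over shLuc and that of shFox2-2 over shGFP had a Pearson r of -0.003 and a covariance of -0.00022. With the controls exchanged, r was 0.067 and the covariance 0.0046.

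RBFOX2 binding was described from 35639 iCLIP clusters in 7740 genes by the submitters' gene IDs. By these IDs the genes with the most clusters were Galnt2, a glycosyltransferase gene (149), Smyd3, a methyltransferase gene (136), Exoc4, of the exocyst (102), the receptor gene Fgfr2 (101) and the oxidoreductase gene Wwox (99). They were followed by Dgcr8, the microRNA microprocessor subunit (85), Immp2l (80), Rbpj (78), the PAS-domain kinase gene Pask (76) and the recombination gene Rad51b (69). Only 13 of the Galnt2 clusters, 5 of those of Fgfr2 and 7 of those of Immp2l lay in the locus that the expression table gives for the gene. The clusters of Dgcr8 merged into 9 regions, those of Rbpj into 12, those of Pask into 5 and those of Smyd3 into 101, since clusters overlapped. The counts make no allowance for gene length. The loci of Smyd3, Exoc4, Wwox and Rad51b span 563, 724, 913 and 517 kb, so the ranking does not measure strength of binding. Rbfox2 itself carried 51 clusters by gene ID and 50 by locus.

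The clusters of highest coverage, as the authors gave it, lay in Uri1 (chromosome 7, 38792124 to 38794263, coverage 202869, 6.76-fold over untagged) and Tsix (X, 100643253 to 100645334, coverage 152460, 3.17-fold). Next were clusters in Usp30 (5, 114567664 to 114568919, 4.62-fold), Pias2 (18, 77361475 to 77362937, 6.52-fold) and Cabin1 (10, 75171470 to 75173281, 5.41-fold). Uri1 encodes a prefoldin-like protein and Tsix the antisense RNA of Xist. In the most covered clusters, background shared with the untagged library could not be told apart from binding. Over all clusters the median length was 91 nt (33 to 3155) and the median coverage 374. In 16000 clusters (44.9%, 95% interval 44.4 to 45.4) the untagged library had no coverage, and in the rest the median fold was 3.67. The lowest fold was 1.05, and 4162 clusters (11.7% of all) lay under 2-fold. A locus of the expression table was overlapped by 91.2% of clusters, and 73.9% lay wholly inside exactly 1 locus.

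The next comparison asked whether RBFOX2 bound the RNAs of RNA-binding proteins more often than those of other genes. Clusters were found in 193 of 221 expressed RBP genes (87.3%, 95% interval 82.2 to 91.4), against 54.1% of other expressed genes. Given FPKM and locus length, 72.9% were expected (p = 1e-05, the smallest that the permutations could give). Among other splicing regulators 57 of 62 genes had clusters (adjusted p = 0.00324), with Clk4, Pnn, Rbm22, Rbm45 and Rbmx as the exceptions. Other mRNA-binding regulators had clusters in 54 of 60 genes (adjusted p = 0.0218), with 85 clusters in Dgcr8 and 30 in the locus of Msi2, a Musashi protein gene named after its value was seen. Clusters were present in 24 of 26 hnRNP genes (adjusted p = 0.0736), with Hnrnpa2b1 and Hnrnpll as exceptions, and in 10 of 12 SR protein genes (adjusted p = 0.428). The spliceosome core had 35 of 44 (adjusted p = 0.489), NMD and exon junction complex genes 12 of 16 (adjusted p = 0.564) and RBPs known to make NMD isoforms 27 of 32 (adjusted p = 0.317).

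**Figure D3:**
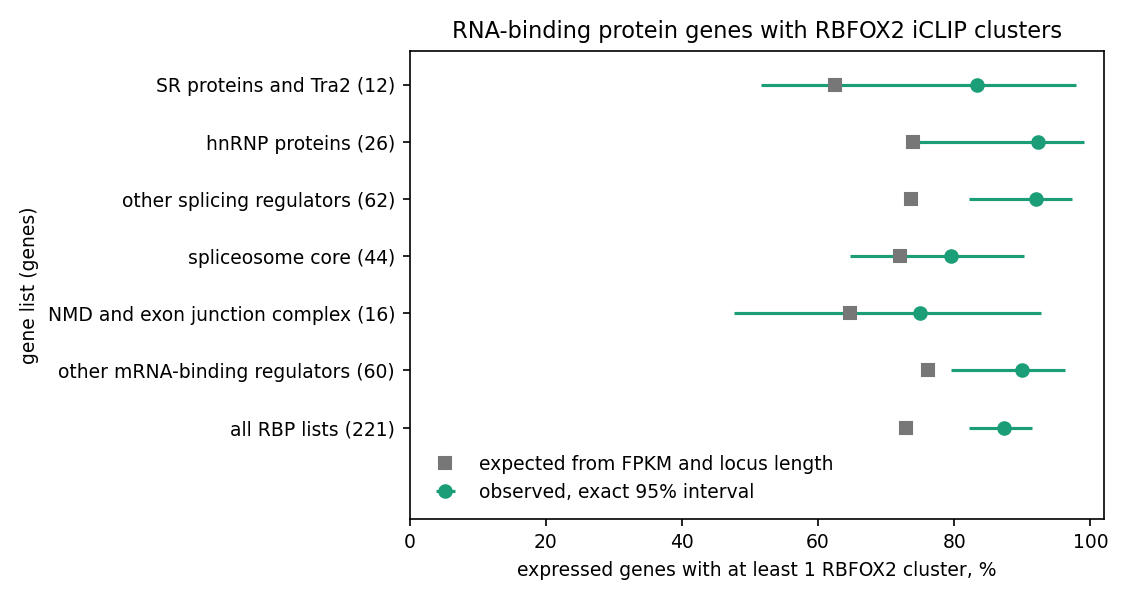
Percent of expressed genes with at least 1 RBFOX2 cluster in each RBP list (circles, with exact 95% intervals) and the percent expected from FPKM and locus length (squares). All RBP lists together lie at 87.3% against 72.9% expected.

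The joined data were used to ask whether the FPKM of genes with clusters responded to the knockdown. With 1 value per gene and hairpin, a change in splicing or between isoforms of a gene was not measured. Among separated genes with clusters were Wdr35 (6 clusters), Rbpj (78), Mdm2 (6), Sar1a (3) and Limk2 (8) on the higher side. On the lower side were Rbfox2 (50), Itga3 (2), Pls3 (2), Ptms (5) and Slc1a5 (2). Rbfox2 is the target of the hairpins, so its fall is not a response of a bound gene. It is counted below among all separated genes and among the lower genes with clusters. Of the separated RBP genes Srsf7 had 3 clusters, Hnrnpab 3 and Pcbp2 8, while Hnrnpa2b1 had 0. Clusters were present in 31 of 37 separated genes (83.8%, 95% interval 67.99 to 93.8) against 74.4% expected from FPKM and length (permutation p = 0.178). For the higher genes the count was 21 of 22 (permutation p = 0.0865) and for the lower genes 10 of 15 (permutation p = 1.0). The higher genes passed with clusters in the upper part of the coverage distribution (20 of 22, permutation p = 0.0263), with gene IDs (permutation p = 0.0298) and in strata of FPKM only (permutation p = 0.00059), and not in the other 4 settings (permutation p = 0.0536 to 0.492). With the submitters' gene IDs the p over all separated genes was 0.0418, and in strata of FPKM only it was 0.00546.

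The median log2 fold change of genes with clusters exceeded that of genes without by 0.026, and permutation within the strata gave 0.024 (p = 0.555). By number of clusters, medians were -0.02 with 0, -0.01 with 1, -0.0038 with 2 to 4, 0.02 with 5 to 9 and 0.02 with 10 or more. In strata of FPKM only the difference passed the test (p = 0.0001, the smallest that the permutations could give). Without shLuc the difference was 0.036 (permutation p = 0.0466), without shGFP it was 0.024 (permutation p = 0.671), without shFox2-1 it was -0.017 (permutation p = 0.0002), and without shFox2-2 it was 0.071 (permutation p = 0.0001). The pairings that do not group the knockdown hairpins also passed this test within the strata, at -0.047 and 0.027 (permutation p = 0.0001 and 0.0003). A pass is therefore not particular to the knockdown. Among RBP genes with clusters the median was 0.01 against 0.02 in random lists of genes with clusters (permutation p = 0.50). In that group 4 of 193 genes with clusters, the targeted Rbfox2 among them, and 1 of 28 without were separated (Fisher's exact p = 0.495).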

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

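The comparison of the 2 knockdown hairpins with each other and the count of genes that moved in opposite directions were chosen after the data were examined, as was the centred count, while the tests of the other pairings and of the side of each list were set before their results were seen, but after the list medians were.

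The 2 knockdown hairpins differed from each other in several gene groups although Rbfox2 itself stood at 35.7% of control in shFox2-1 and 30.0% in shFox2-2. Pluripotency genes had a median log2 difference of -0.49 in shFox2-2 over shFox2-1, other splicing regulators -0.31, other mRNA-binding regulators -0.31 and the joined RBP lists -0.27. Part of this is an offset of all genes, since matched random lists had medians of -0.12 to -0.13. Each difference stood apart from them (adjusted p = 0.000867 over 26 lists). These 4 lists were chosen because their medians lay on opposite sides of both controls in the 2 hairpins, also after centring. An adjusted p under 0.05 was a second condition of the choice. NMD and exon junction complex genes met only the first condition (adjusted p = 0.209 against matched random lists). So did RBPs known to make NMD isoforms (adjusted p = 0.0634). Only the direction is thus a result, above both controls in shFox2-1 and below both in shFox2-2. Cholesterol synthesis (0.31) and glycolysis and hypoxia (0.18) had the same adjusted p and went the other way. Their matched random lists had medians of -0.18 and -0.12. Centred, the joined RBP lists lay at 0.065 and 0.074 over the controls in shFox2-1 and at -0.060 and -0.063 in shFox2-2. Nanog, a core factor of ES cells, stood at 77.9 and 81.5 FPKM in the controls, 136 in shFox2-1 and 76.0 in shFox2-2. Tfcp2l1 and Tbx3, factors of the naive ES state, stood at 12.8 and 12.6 against 25.2 and 11.96, and at 5.10 and 5.24 against 14.5 and 5.51. In shFox2-2, Nanog and Tfcp2l1 thus lay close to the controls and Tbx3 above both. No member of the pluripotency list lay beyond both control intervals on opposite sides in the knockdown hairpins. In all, 12 of the 26 lists differed between the knockdown hairpins and 4 between the control hairpins, among the latter other splicing regulators and the joined RBP lists (adjusted p = 0.0455 each).

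In 59 genes, of which those named were chosen after their values were seen, the knockdown hairpins lay beyond both control intervals on opposite sides, a pattern not tested beyond these intervals. In 58 of them shFox2-1 was the higher hairpin, and the exception was Ctsl, which encodes cathepsin L. The median gene itself differed by -0.16 in log2 in shFox2-2 over shFox2-1. After centring on it the genes numbered 23, with shFox2-1 higher in 15 and lower in 8, and 16 of them, with Ctsl, Tet2, Rif1 and Atrx, were among the 59. The methylcytosine dioxygenase gene Tet2 stood at 5.05 and 5.21 FPKM in the controls, 11.5 in shFox2-1 and 3.45 in shFox2-2. Rif1, a regulator of replication timing, stood at 36.3 and 35.0 against 48.6 and 19.5, and the chromatin remodeller gene Atrx at 37.6 and 34.6 against 49.6 and 23.0. Several others, among them Rex2, Zfp979, Zfp980 and Zfp981, lie near each other on chromosome 4 and belong to zinc finger families whose similar copies can share reads, which was not tested.

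Gene lists stood apart from random lists in the knockdown hairpins, 9 of 26. The other pairings of the hairpins called 12 and 9 lists, so a number as large arose without grouping the knockdown hairpins, and spread between hairpins could account for it. Of the 9 lists, a share of 0.556 had both knockdown medians on the same side of both controls as deposited (the 2-cell-like state, unfolded protein response, neuronal, glycolysis and ribosomal lists). That share lies between the values set for and against an origin in 1 hairpin, which therefore cannot be told apart from an effect of both. Which lists these are depends on centring. Centred on the median gene, the unfolded protein response left the group and p53 targets entered it. Glycolysis and hypoxia then lay at only -0.009 and -0.004 over shLuc and shGFP in shFox2-2. An effect of the Rbfox2 knockdown, or of a hairpin on other targets, stays open and was not tested separately.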

How the results depend on the processing

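The interval criterion, the gene-ID assignment, the status and joint centring alternatives and leaving out each hairpin were chosen after the data were examined. Across settings, 197 values kept their side of the threshold and their direction relative to random lists or the expected share, though in 8 of these the value itself changed sign. In 41 the direction reversed. The cause was not tested for values that changed unless stated. At an adjusted p under 0.05, limma called 0 of all tested genes (908 unadjusted), and 0 after centring (1119), with status OK (731), without a pseudocount (773) or without any hairpin (720 to 2980). A threshold of 0.1 gave 1 gene without a pseudocount and 0 in the others of these tests. In a fit over genes at FPKM of 1 or more, 1 gene passed, Rbfox2 at -1.496 (adjusted p = 0.0471, 541 unadjusted), and with centring 1 again, at -1.49 (0.0466, 720 unadjusted). The unadjusted limma p of Rbfox2 was 3.73e-06 in that fit without centring, against 6.82e-05 over all tested genes. The call therefore does not rest on the smaller number of genes alone. Each of the other 2 pairings also called 1 gene at FPKM of 1 or more (449 and 931 unadjusted), at lower limma adjusted p-values of 0.000151 and 2.77e-06. Over all 20281 tested genes, 1 of these pairings called 1 gene (limma adjusted p = 0.00864). Since no gene passed 0.01 or 0.1 over all tested genes, the tests that join clusters to called genes gave no value at these thresholds.

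Leaving out a hairpin set fewer conditions and separated 106 to 954 genes (106 without shLuc, 118 without shGFP, 294 without shFox2-1, 954 without shFox2-2). In limma fits without a hairpin, the lone one left is assumed to vary like the other group. Lists called ranged from 5 without shLuc to 14 without shFox2-2. List medians ranged from -0.033 to 0.26 for SR proteins, -0.14 to 0.15 for other splicing regulators, -0.17 to 0.081 for the spliceosome core, -0.16 to 0.14 for other mRNA-binding regulators, -0.12 to 0.20 for RBPs with NMD isoforms, -0.17 to 0.19 for NMD and exon junction genes, -0.11 to 0.096 for hnRNP proteins and -0.15 to 0.14 for all RBP lists, the last called lower without shFox2-1 and higher without shFox2-2. The spliceosome core and other mRNA-binding regulators were called lower without shFox2-1, and SR proteins, other splicing regulators and RBPs with NMD isoforms higher without shFox2-2. They ranged from -0.20 to 0.31 for pluripotency, called lower without shFox2-1 and higher without shGFP or shFox2-2, -0.19 to -0.053 for neural genes, called lower without shFox2-1, -0.074 to 0.36 for trophoblast, 0.083 to 0.19 for the 2-cell-like state, 0.030 to 0.29 for p53 targets and -0.20 to -0.044 for the unfolded protein response. Further ranges were -0.20 to 0.046 for the cell cycle, -0.12 to -0.071 for neuronal genes, -0.22 to -0.046 for glycolysis, -0.37 to -0.038 for cholesterol synthesis, -0.15 to -0.040 for imprinted genes, -0.064 to -0.0020 for mesoderm, -0.12 to 0.12 for endoderm, -0.069 to 0.039 for fibroblast, -0.10 to -0.0038 for interferon response and -0.17 to -0.11 for ribosomal proteins. Among lists called with all hairpins, trophoblast, cholesterol synthesis and the unfolded protein response reversed relative to random lists without shFox2-1. Imprinted genes, not called with all hairpins, reversed without each hairpin and were called without shFox2-2.

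With status OK required, the 2-cell-like list (0.087, adjusted p = 0.0587), cell cycle (-0.083, 0.0770) and neuronal genes (-0.12, 0.0770) lost their call, as did neuronal genes at FPKM of 1 or more (-0.14, 0.115). Pluripotency gained one with matching on length (0.072, adjusted p = 0.0395). With status OK, 3 RBP genes were separated (permutation p = 0.0602). The 83.8% of separated genes with clusters passed with gene IDs (permutation p = 0.0418) and with strata of FPKM only (permutation p = 0.00546), where length is not held. The following reversed without being called in either setting: hnRNP proteins (-0.0023) with status OK, other splicing regulators (0.012) with matching on length, other mRNA-binding regulators at FPKM of 1 or more (0.0043), without a pseudocount (0.0060) and with status OK (0.0027), fibroblast (-0.15) and interferon response (-0.089) at FPKM of 1 or more, interferon response (-0.096) without a pseudocount, genes with clusters at an unadjusted p under 0.05 (52.9%) and the fold difference of genes with clusters with status OK (0.019). The 0.026 difference in fold change of genes with clusters passed with FPKM strata only and without shLuc (0.036), and it ranged from -0.017 without shFox2-1, where it reversed (permutation p = 0.0002), to 0.071 without shFox2-2. Clusters in a locus fell from 91.2% to 73.9% when they had to lie wholly inside exactly 1. The enrichment of clusters in RBP genes held in each setting run. No paired analysis was possible because the columns pool the replicates of a hairpin. Motif, gene-strand, per-library and count-based alternatives were not run. Unknown depth limits what can be said of genes at low FPKM.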

Other observations

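Genes in these paragraphs were picked after their values were seen, as were the tests of log2 q against coverage and of the pairings that separate genes. The tests on genes with clusters were set before their results were seen, but after the medians by number of clusters were.

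Among separated genes not described so far, Scd1, a fatty acid desaturase gene, stood at 19.6 and 20.0 FPKM in the controls and at 15.4 in each knockdown hairpin, a log2 fold change of -0.34. The microtubule-binding gene Map1b had a log2 fold change of -0.37 and the teneurin gene Tenm3 of -0.42. The phosphatase gene Ptpn14, with 61 clusters, rose from 13.3 FPKM in each control to 17.9 and 16.8, the clathrin adaptor gene Ap2b1 had a log2 fold change of 0.35, and Ash2l, of histone methyltransferase complexes, of 0.31. With hairpins centred, Scd1, Tenm3 and Ash2l were not separated. In the pluripotency list, both knockdown values lay above both controls in 6 of 34 members and below both in 4. Of all genes 16.7% would be ordered each way only if hairpins were interchangeable. Of the 4 members below both controls, Fgf5 stood at 2.60 and 2.25 FPKM against 0.777 and 1.43, Otx2 at 10.1 and 9.63 against 6.59 and 7.49, and the DNA methyltransferase gene Dnmt3b at 96.8 and 107 against 59.7 and 84.3. Their unadjusted limma p-values were 0.0140, 0.0243 and 0.0324, and no gene of the list was called when adjusted over the list alone.

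Binding outside the RBP lists was enriched in neuronal and synaptic genes, where 17 of 17 expressed members had clusters against 11.6 expected from FPKM and length (adjusted p = 0.0129, permutation test). Ank3 carried 18 clusters and Cacna1a 16. Cytosolic ribosomal protein genes had clusters in 31 of 52 against 20.0 expected (adjusted p = 0.00632). Of 8 expressed histone genes 0 had clusters, against 0.280 expected. In the naive ES cell gene Tfcp2l1 there were 15 clusters, and in Esrrb 22.

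Genes with RBFOX2 clusters lay slightly higher in the knockdown hairpins, with a difference in median log2 fold change of 0.026. Within strata of FPKM and locus length the difference did not pass the permutation test (p = 0.555), so gene length and expression could account for it with all 4 hairpins. The other pairings of the hairpins gave differences of -0.047 and 0.027, each larger in size than that of the knockdown. Both passed the permutation test within the strata (p = 0.0001 and 0.0003). Spread between hairpins could therefore give the difference as well, and a pass does not set the knockdown apart. The difference was 0.036 without shLuc, 0.024 without shGFP, -0.017 without shFox2-1 and 0.071 without shFox2-2. A direct effect of Rbfox2 on bound mRNAs stays open.

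The q-values of clusters with no untagged coverage followed the coverage exactly, with log2 q divided by coverage at a median of -1.0 (lowest -1.0, highest -1.0, 15413 clusters with q above 0). Coverage per nucleotide of cluster was 1.5 at the lowest and 4.01 at the median. A candidate explanation is that coverage counts bases rather than reads, so that each read entered the test many times over and the q-values are smaller than read numbers would give. The ratio of -1.0 relates q to coverage whatever coverage counts, so it cannot tell bases from reads. No biological explanation was tested.

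In the 356 most covered clusters the interquartile ratio of fold over the untagged library was 1.69, against a median of 3.10 in draws of as many other clusters (lowest 2.49). Their median fold was 6.58. The draws were not matched on coverage, so the narrower range may go with high coverage alone. The ratio of 1.69 lay between the values set for and against background shared by both libraries. Such background therefore cannot be told apart from binding here. The knockdown pairing separated 37 genes, which was reached in 1 of the 3 pairings, and the highest of the others separated 16, and 3 pairings are too few for a share under 0.05.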
